A study of Mus musculus with 8 samples.

How the data were processed

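The series holds 8 reduced representation bisulfite sequencing (RRBS) libraries of mouse embryonic stem cells, with 1 library for each of 4 treatments on day 2 and day 5. RRBS sequences DNA fragments released by a restriction enzyme after bisulfite treatment, which converts unmethylated cytosine to uracil, so that a cytosine still read as C is counted as methylated. Bisulfite sequencing does not tell 5-methylcytosine from 5-hydroxymethylcytosine. Each library was assigned to its treatment and day from its label.

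CASAVA and BSMAP 2.88 and the mouse build mm9 are named in the submitters' processing notes, which as used here do not give their roles, settings or order. The deposited files list, for each CpG, its position, the fraction of reads methylated and the coverage in reads. The fraction is the value the authors deposited, from 0 to 1, with no normalization stated in the sources used here. The coverage deposited beside it has a minimum of 10 reads in every file and is a whole number for 99.3% to 99.6% of CpGs per library; the others were rounded. All listed CpGs carry the same strand sign, so the strands could not be summed separately. How duplicates, overlapping mates and incomplete conversion were treated is not given in the sources used here.

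From these values the methylated reads of each CpG were taken as coverage times fraction, rounded to a whole number. Among CpGs with coverage up to 300 reads, at least 99.98% of these products lay within 0.0005 times the coverage of a whole number in every library, the rounding of the deposited fraction. Percentages of methylation were computed from these reads. The main set was the 622768 CpGs on chromosomes 1 to 19, X and Y with at least 10 reads in all 8 libraries. It made up 62.0% to 81.9% of each library's CpGs on these chromosomes. Median coverage in this set ranged from 27 to 56 reads per library. The files also list a contig named lambda, the mitochondrial genome and unplaced contigs, which were kept apart from the comparisons.

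Mean methylation was the mean of CpG percentages over the main set. For vitamin C, for L-proline and for day, 4 matched differences were formed between libraries that shared the other factors. Their mean and SD are given with an exact two-sided sign-flip permutation test over 16 sign assignments, for which the smallest possible p is 0.13. With 1 library per treatment and day there is no replicate of any group, and the spread between matched pairs holds both real differences in effect and noise. The labels name no culture or batch. The day 2 and day 5 libraries of a treatment may share a culture, so the 4 pairs may not be independent. PCR reads without molecular identifiers are not independent molecules, so intervals and Fisher tests cover counting error only.

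Pairs of libraries were compared at each CpG with a two-sided Fisher's exact test on methylated and unmethylated reads, in 14 comparisons. A CpG was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison and a difference of at least 20 percentage points. These tests compare libraries, not conditions. Across libraries, reads were summed over fixed tiles of 1 kb with at least 3 CpGs of the main set, giving 50167 tiles. The log2 ratio of methylated to unmethylated reads, with a pseudocount of 1 added to each, was fitted in limma 3.58.1 with additive terms for vitamin C, L-proline and day. The fit has 4 residual degrees of freedom and assumes that the effects add. A tile was called at an adjusted p under 0.05 and a difference of at least 10 percentage points. A vitamin C by L-proline term was tested in the same way with 3 residual degrees of freedom.

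The procedures were tested on simulated data. For the vitamin C term of the limma fit over 50167 tiles, with few tiles changed, 0% of tiles changed by 20 points, 34.0% of those changed by 30 points and 98.0% of those changed by 40 points were recovered. With 3000 tiles changed by 20 points and 3000 by 10 points, 26.5% and 0.667% were recovered, with 2 unchanged tiles called. Noise between libraries was drawn separately for each tile, without a shift of a whole library. These rates and false calls therefore do not cover such shifts. For the Fisher comparison of vitamin C with untreated on day 5 over 622768 CpGs, 4% of the CpGs changed by 40 points and 14% of those changed by 50 points were recovered, with 0 unchanged CpGs called. The reads of both libraries were drawn with counting error alone, so these 0 calls do not cover variation between libraries. Small changes were therefore outside the reach of both tests when few sites changed.

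The rule for the named tiles was fixed before the data were examined. For vitamin C and for L-proline it takes the 5 largest mean matched gains and the 5 largest losses among called tiles that moved in the same direction in all 4 pairs. In a direction with fewer than 5 such called tiles, it takes the largest among all tiles with the same direction in all 4 pairs, said not to pass. Classes of CpGs and tiles were set by the mean over all 8 libraries, by untreated cells of the day not compared, by the number of covered CpGs per tile and by chromosome. Alternatives covered the coverage minimum, the set of CpGs, pooled reads, thresholds, tile size, CpGs per tile, pseudocount, scale, model, centring of libraries and leaving out each library in turn. Thinning to 20 reads, library quality weights, classes by untreated cells of the day not compared, the gap of X to autosomes at 20 reads and the terms for an interaction with day were added after the data had been seen. Promoters and gene lists were not analysed here, because no annotation of the build of the files was at hand and coordinates were not converted between builds. Tiles are therefore named by position in mm9, counted from 1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 and R 4.3.3 were used.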

Results

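DNA methylation was measured by RRBS in mouse embryonic stem cells of strain 129/SvP, grown at low density in fetal bovine serum with leukaemia inhibitory factor (FBS/LIF), a cytokine that maintains self-renewal. Cells were left untreated or received 1 mM L-proline, 500 µM vitamin C or both, and were collected on day 2 and day 5. Vitamin C is a cofactor of dioxygenases, among them the TET enzymes, which oxidise 5-methylcytosine. The title of the series frames the supplements as antagonists, so the comparisons asked how each supplement, their combination and time in culture related to CpG methylation. Each treatment and day had 1 library. The libraries listed 762041 to 1006832 CpGs at 10 or more reads, and the main comparisons used the 622768 CpGs covered in all 8. On the contig named lambda, customarily an unmethylated control, 0.195% to 0.513% of cytosines were read as methylated over 842 to 8888 reads per library.

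Methylation was lower in every library with vitamin C than in its matched library without it. Without vitamin C, mean CpG methylation on day 2 was 19.04% in untreated cells and 21.3% with L-proline, and on day 5 it was 21.2% and 24.0%. With vitamin C it was 16.8% alone and 18.3% with L-proline on day 2, and 16.1% and 17.8% on day 5. The mean matched difference for vitamin C was -4.14 ± 1.82 percentage points (SD, n = 4 pairs), lower in 4 of 4 pairs. The differences were -2.25 on day 2 and -5.15 on day 5 without L-proline, and -3.02 and -6.16 with it. Over all CpGs listed for each library, the day 2 difference with L-proline was -0.187. The exact sign-flip permutation test gave p = 0.13, the smallest this design allows. Over pooled reads, the lowest library was vitamin C on day 5 at 11.59% (95% Wilson interval 11.58 to 11.61) and the highest L-proline on day 5 at 20.97% (20.95 to 20.98). With a minimum of 30 reads the mean matched difference for vitamin C was -1.97 points. The mean without vitamin C was then 8.38%, against 21.4% in the main set, so points are not directly comparable between these sets.

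**Figure D1:**
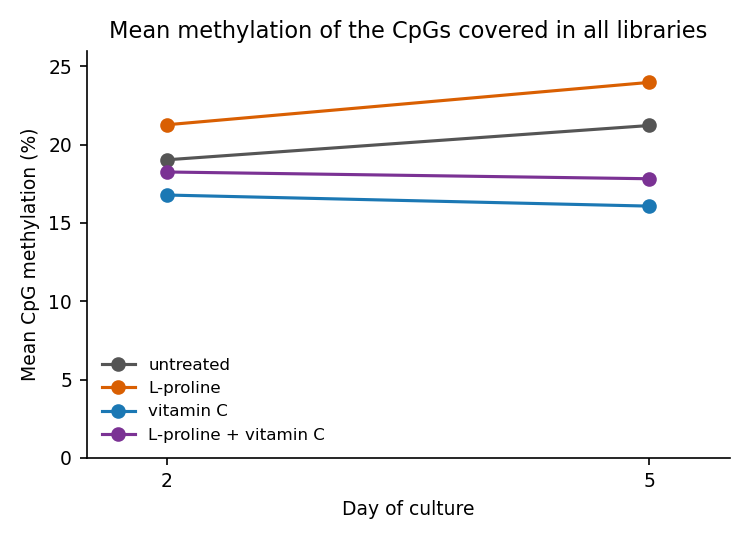
Mean CpG methylation (percent, vertical axis) of the 622768 common CpGs against day of culture, with 1 point per library and lines joining the libraries of a treatment. The vitamin C libraries lie lowest, at 16.8% on day 2 and 16.1% on day 5, and the L-proline libraries highest, at 21.3% and 24.0%.

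The difference with vitamin C was present from low to high methylation. In a classing added after the data had been seen, CpGs were placed by untreated cells of one day and compared on the other, so that the classing library entered no difference. Those at 20 to 40% differed by -16.8 ± 9.53 points (SD, n = 4 pairs), those at 40 to 60% by -17.96 ± 8.20 and those at 60 to 80% by -15.7 ± 5.52. CpGs at 80 to 95% differed by -10.2 ± 2.79 points, those at 95% or above by -7.17 ± 1.60 and those at 5 to 20% by -7.30 ± 5.18. CpGs under 5%, with little methylation to lose, differed by -0.500 ± 0.415. Classed by the mean over all 8 libraries, CpGs of 20 to 80% held 58.0% of the overall difference, those of 80 to 95% 22.6% and those of 5 to 20% 13.5%. By CpG density, tiles with 3 to 5 covered CpGs differed by -11.0 ± 4.70 points and those with 41 or more by -0.268 ± 0.176, with mean methylation in untreated cells on day 2 of 57.9% and 0.725%. The difference ranged from -4.61 to -3.81 points over the 19 autosomes. On chromosome X it was -2.87 ± 1.12 points, and for X-linked CpGs of mean methylation 20 to 80% it was -15.6 ± 5.44 against -18.6 ± 8.09 on autosomes. The gap within pairs was 2.98 ± 2.81 points for these CpGs, smaller in loss on X in 3 of 4 pairs (exact sign-flip permutation p = 0.25), and 1.28 ± 0.734 over all CpGs, in 4 of 4 pairs (p = 0.13 in the same exact test). With a minimum of 20 reads, which left 1243 CpGs on X, the gap over all CpGs turned to -0.581 ± 0.323, a larger loss on X in 4 of 4 pairs. For CpGs of mean methylation 20 to 80% (168 on X) it stayed positive at 1.86 ± 3.07, in 3 of 4 pairs. In untreated cells on day 2, X averaged 15.55% in the main set and 16.9% at 20 reads, and all chromosomes together 19.04% and 11.3%. The contrast over all CpGs therefore depended on the CpGs kept and their levels.

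**Figure D2:**
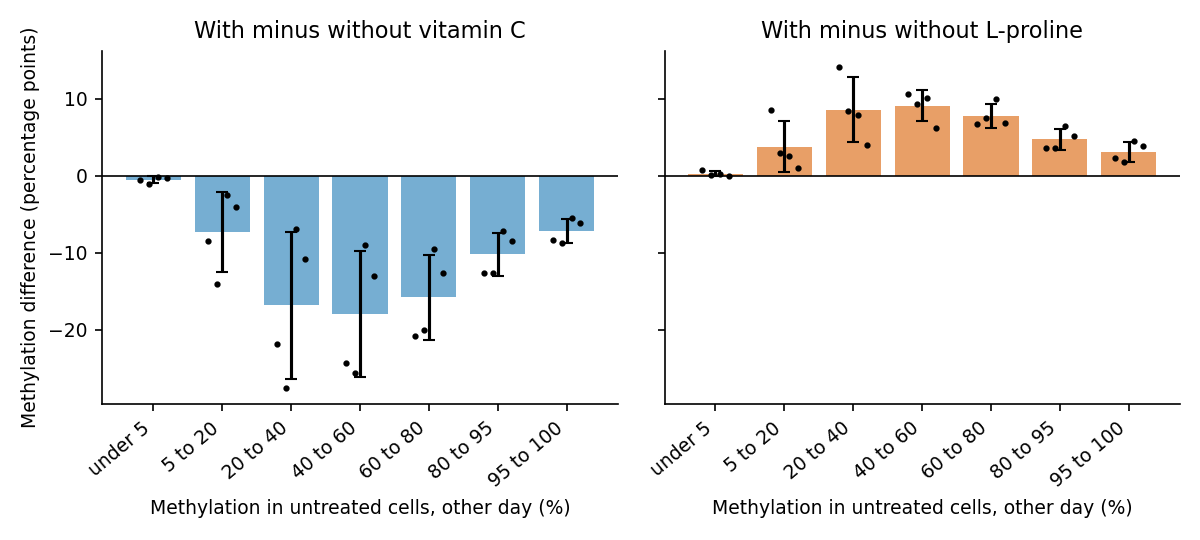
Difference in CpG methylation (percentage points, vertical axis) with minus without vitamin C (left) and L-proline (right), by the methylation of the CpG in untreated cells of the day not compared (percent, horizontal axis). Bars are means of 4 matched pairs, error bars their SD and dots the pairs; the class of 20 to 40% differs by -16.8 points for vitamin C and 8.59 for L-proline.

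In the limma fit over 50167 tiles, 11645 tiles (23.2%) lost methylation with vitamin C and 0 gained it, with a median difference of -18.5 points among those called. Of these, 11094 were lower in all 4 pairs. Tiles of a library can shift together, which the adjusted p does not allow for. The count is therefore not a count of independent changes. For the mean over CpGs, the exact sign-flip permutation test gave p = 0.13. At an unadjusted p under 0.05, 23949 tiles were lower and 295 higher. On chromosome X, 56 of 596 tiles (9.40%) were called. The count was 7650 without the L-proline plus vitamin C library of day 2, and without the day 5 libraries it was 3130 (untreated), 4748 (L-proline), 3733 (vitamin C) and 2742 (both). A quasi-binomial model called 534 tiles, all lower. Centring each library to one median called 932 higher and 135 lower. Centring subtracts the same shift from every tile of a library (library medians ran from -3.04 to -0.07 on the log2 scale). The difference in points was not the same across tiles, so these gains are relative to that shift.

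The largest called loss was in the tile on chromosome 4 from 57858001 to 57859000 (4 CpGs, 70 to 195 reads per library), which averaged 91.1% without and 31.4% with vitamin C, a difference of -59.7 ± 17.9 points (SD, n = 4 pairs; limma adjusted p = 0.0106). The tile on chromosome 4 from 55021001 to 55022000 (3 CpGs) averaged 81.1% without and 24.6% with it, a difference of -56.5 ± 17.7 points. On chromosome 10, the tile from 75328001 to 75329000 (4 CpGs) averaged 68.1% and 12.9%, differing by -55.2 ± 20.1 points. On chromosome 6, the tile from 76447001 to 76448000 (5 CpGs) averaged 76.1% and 21.9%, differing by -54.2 ± 17.4 points. On chromosome 7, the tile from 29997001 to 29998000 (4 CpGs) averaged 68.1% and 14.0%, differing by -54.1 ± 17.5 points. These tiles had the same limma adjusted p of 0.0106, and none of the 5 passed with the quasi-binomial model. No call was made for a gain, and 86 tiles were higher at an adjusted p under 0.05 with no minimum difference. Among tiles higher in all 4 pairs the differences were at most 8.55 ± 6.72 points, on chromosome 5 from 122303001 to 122304000, where limma gave an adjusted p of 0.136. The next were chromosome 5 from 110447001 to 110448000 (7.05 points), chromosome 17 from 65706001 to 65707000 (6.56), chromosome 2 from 152512001 to 152513000 (6.39) and chromosome X from 100162001 to 100163000 (5.96), none of which passed. All 5 passed when the libraries were centred to one median, a shift applied to every tile whatever its own difference.

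Between single libraries, Fisher's exact test called 3034 CpGs lower and 164 higher with vitamin C than without on day 2, and 18390 lower and 26 higher on day 5. Of the 3034 lower CpGs of day 2, 721 were also called lower on day 5. In the 81860 CpGs whose levels allowed a loss of 20 points on both days, 2427 were called lower on day 2 and 14237 on day 5. Independent lists of these sizes would share 422. This number does not allow for coverage, which affects the calls of both days. The day 5 difference over these 3034 CpGs averaged -25.0 points, and 91.2% of them were lower. Between the same day 5 libraries, all CpGs at 20 to 40% in untreated cells of day 2 differed by -21.8 points. Those at 40 to 60% differed by -24.2, those at 60 to 80% by -20.8 and those at 80 to 95% by -12.6. Among the 348979 CpGs with 20 or more reads in all libraries, 1641 were called on day 2 and 9382 on day 5, and 6 and 700 when these were thinned to 20 reads.

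Methylation was higher in every library with L-proline than in its matched library without it. The mean matched difference was 2.05 ± 0.565 percentage points (SD, n = 4 pairs), higher in 4 of 4 pairs. The differences were 2.24 on day 2 and 2.75 on day 5 without vitamin C, and 1.47 and 1.75 with it. The exact sign-flip permutation test gave p = 0.13, the smallest this design allows. Classed by untreated cells of the other day, CpGs at 20 to 40% differed by 8.59 ± 4.21 points, those at 40 to 60% by 9.10 ± 2.00 and those at 60 to 80% by 7.76 ± 1.52. Those at 80 to 95% differed by 4.72 ± 1.39 points, those at 95% or above by 3.12 ± 1.26, those at 5 to 20% by 3.79 ± 3.33 and those under 5% by 0.272 ± 0.311. The difference ranged from 1.83 to 2.26 points over the autosomes and was 1.40 ± 0.489 on chromosome X. The gap of X to autosomes within pairs was -0.660 ± 0.156 points over all CpGs and -1.95 ± 1.01 for those of mean methylation 20 to 80%, each negative in 4 of 4 (exact sign-flip permutation p = 0.13). With a minimum of 20 reads the gap over all CpGs was 0.210 ± 0.335, positive in 3 of 4. For CpGs of mean methylation 20 to 80% it was then -1.08 ± 2.31, negative in 3 of 4. The overall difference was 5.23 points with all CpGs listed for each library, and 0.923 with a minimum of 30 reads. The mean without L-proline was 22.7% and 6.94% in these sets, against 18.3% in the main set.

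**Figure D3:**
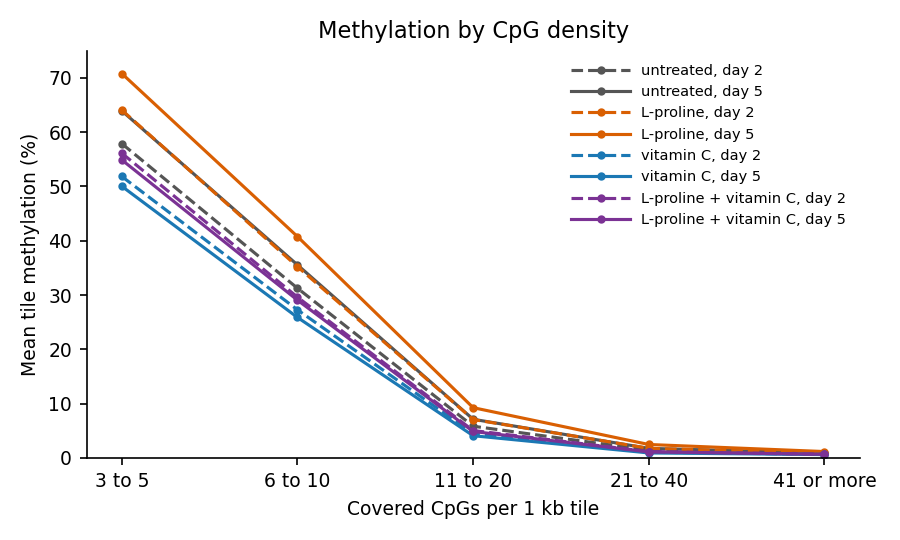
Mean tile methylation (percent, vertical axis) by the number of covered CpGs per 1 kb tile (horizontal axis), with 1 line per library, dashed for day 2 and solid for day 5. In tiles with 3 to 5 CpGs the libraries run from 50.03% (vitamin C, day 5) to 70.8% (L-proline, day 5), and all libraries lie near 1% in tiles with 41 or more.

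No tile passed the limma test for L-proline, where the smallest adjusted p was 0.227. At an unadjusted p under 0.05, 7613 tiles were higher and 385 lower, and the quasi-binomial model called 2. Tiles higher in all 4 pairs numbered 14059 (28.0%) and tiles lower in all 4 pairs 804 (1.60%), where independent pairs with no effect would give 6.25% each. Tiles of a library are not independent of each other, so this is no test. For day the same shares were 11.2% and 2.54%. The largest difference was 37.1 ± 11.9 points on chromosome 6 from 125125001 to 125126000, which averaged 67.6% with and 30.5% without L-proline (4 CpGs; limma adjusted p = 0.227). Next came chromosome 6 from 122617001 to 122618000 (34.97 ± 19.3 points) and from 114674001 to 114675000 (33.5 ± 13.7), chromosome 10 from 69757001 to 69758000 (33.1 ± 19.12) and chromosome 3 from 84014001 to 84015000 (32.6 ± 11.1). In the other direction the values were -14.97 points on chromosome 8 from 48040001 to 48041000, -14.3 on chromosome 7 from 13282001 to 13283000 and -14.2 on chromosome 17 from 26417001 to 26418000. They were -13.2 on chromosome 14 from 51280001 to 51281000 and -13.1 on chromosome 11 from 104676001 to 104677000. None of these 10 tiles passed.

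**Figure D4:**
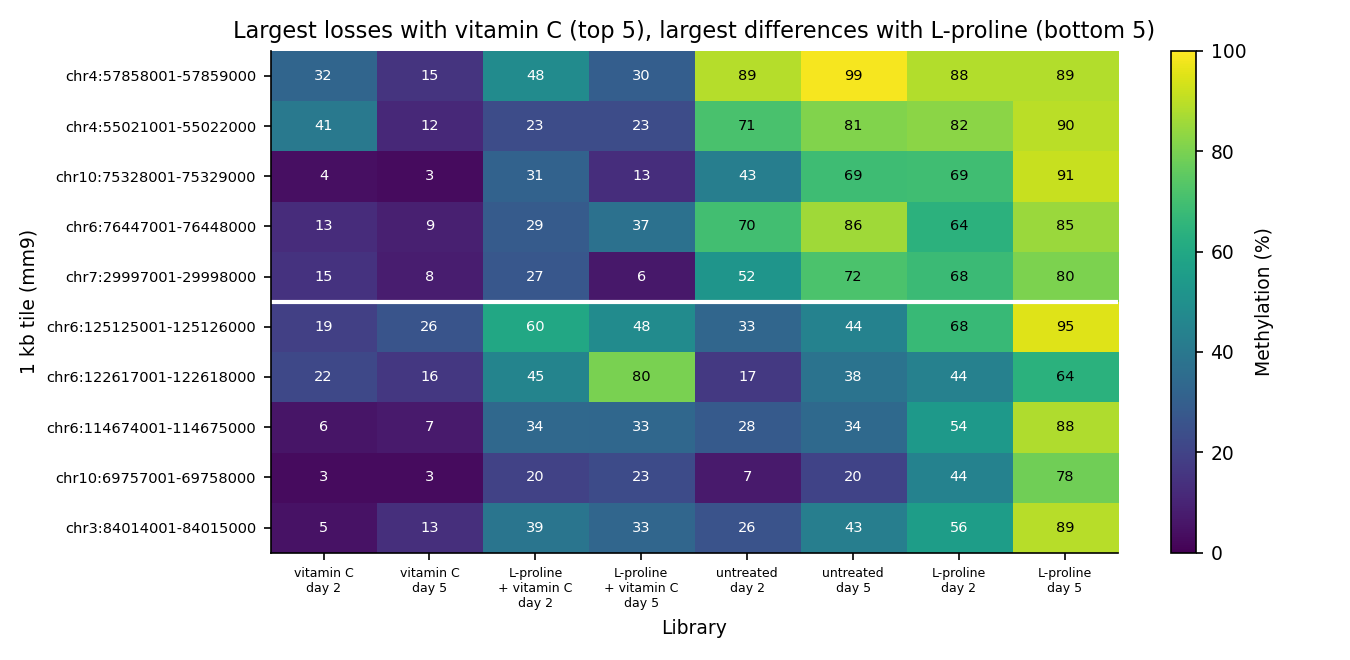
Methylation (percent, colour and printed value) of the 5 tiles with the largest called losses with vitamin C (top) and the 5 with the largest differences with L-proline, which did not pass (bottom). Columns are the 8 libraries; the first tile averages 31.4% in the 4 columns with vitamin C and 91.1% in the 4 without.

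Between single libraries, Fisher's exact test called 594 CpGs higher and 7 lower with L-proline than without on day 2, and 4453 higher and 48 lower on day 5. Of the 594 higher CpGs of day 2, 40 were also called on day 5. In the 60409 CpGs whose levels allowed a gain of 20 points on both days, 399 were called on day 2 and 2974 on day 5. Independent lists of these sizes would share 19.6, without regard to coverage. Of the 594, 82.8% were higher on day 5, by 14.3 points on average over the 594. Between the same day 5 libraries, all CpGs at 20 to 40% in untreated cells of day 2 differed by 14.2 points. Those at 40 to 60% differed by 10.7 and those at 60 to 80% by 6.70. Among the 348979 CpGs with 20 or more reads in all libraries, 407 were called on day 2 and 2817 on day 5, and 0 and 31 when thinned to 20 reads.

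With both supplements, methylation lay between the levels with each alone. It differed from untreated cells by -0.780 points on day 2 and -3.40 on day 5, where the single differences summed to -0.0141 and -2.39. On day 2 the sign depended on the set, with 0.716 points over pooled reads and 4.21 over all CpGs listed for each library (single differences summed to 1.92 and 0.881). Fisher's exact test called 311 CpGs lower and 54 higher than untreated on day 2, and 3722 lower and 36 higher on day 5. Against L-proline alone, 3790 were lower and 10 higher on day 2, and 35293 lower and 75 higher on day 5. Against vitamin C alone, 1999 were higher and 210 lower on day 2, and 543 higher and 24 lower on day 5. Thinned to 20 reads, the calls on day 2 and day 5 were 1 and 40 against untreated (the lone call of day 2 higher), 1 and 1997 against L-proline, and 0 and 2 against vitamin C. On the same CpGs unthinned they were 286 and 2213, 2374 and 17720, and 855 and 339. In the 1678 tiles at least 20 points higher with L-proline than untreated on day 2, adding vitamin C to L-proline gave a mean difference of -29.2 points on day 5 (SD over tiles 14.5), and 98.2% of them were lower. All tiles of the same methylation averaged -24.9. In the 3367 tiles selected on day 5 the difference on day 2 was -12.6 (SD over tiles 8.92), against -11.8 for all tiles of the same methylation. The limma interaction of vitamin C with L-proline called 0 tiles, with 468 higher and 1370 lower at an unadjusted p under 0.05. Together these were 3.66% of tiles, fewer than a threshold of 0.05 gives on average with no effect. This fit holds no vitamin C by day term, so a loss that differs between days enters its residual and can lower this share. The share is therefore no evidence that the supplements do not interact.

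**Figure D5:**
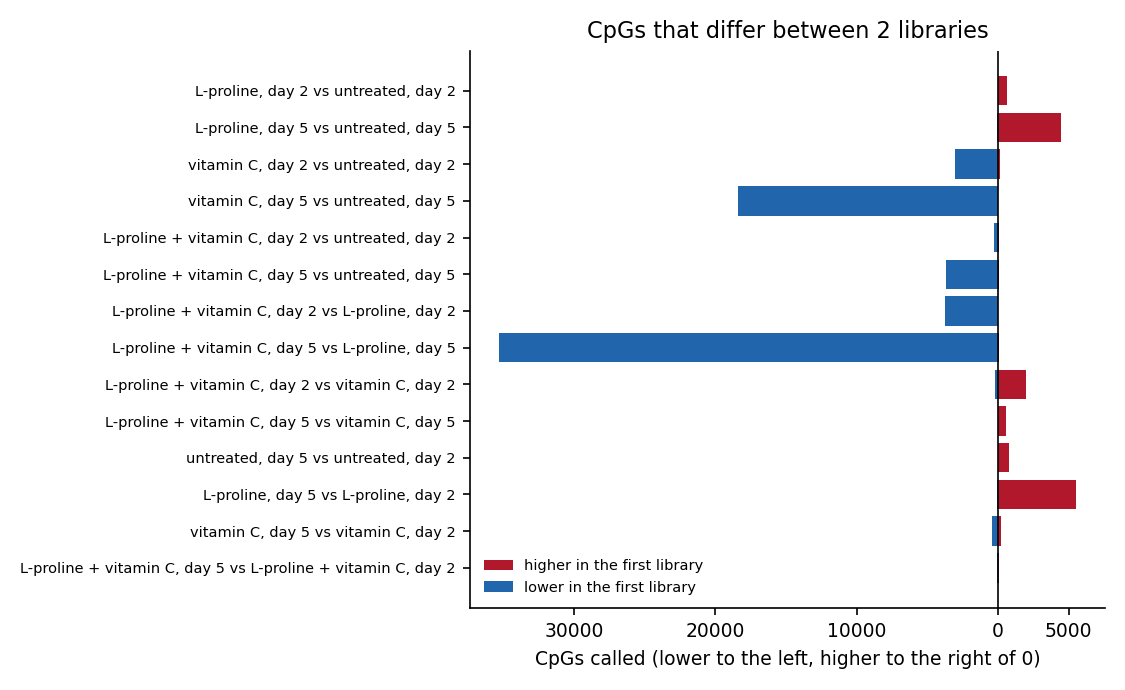
Number of CpGs called by Fisher's exact test in each of 14 comparisons of libraries (horizontal axis, higher in the first library to the right, lower to the left). The longest bar is L-proline plus vitamin C against L-proline on day 5, with 35293 CpGs lower.

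From day 2 to day 5, mean methylation differed by 2.19 points in untreated cells and 2.71 with L-proline, and by -0.708 with vitamin C and -0.432 with both. The mean matched difference for day was 0.939 ± 1.76 points (SD, n = 4 pairs; exact sign-flip permutation p = 0.5), smaller than the spread between pairs. Fisher's exact test called 753 CpGs higher and 12 lower on day 5 in untreated cells, and 5503 higher and 57 lower with L-proline. With vitamin C 192 were higher and 462 lower, and with both 47 higher and 91 lower. Thinned to 20 reads, the calls were 0, 1, 0 and 0 in the same order, against 530, 3713, 358 and 77 on the same CpGs unthinned. The limma fit called 0 tiles for day (smallest adjusted p 0.590), with 3291 higher and 488 lower at an unadjusted p under 0.05, and the quasi-binomial model called 1.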

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

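The tests in this part were chosen after the results they bear on had been seen.

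The change from day 2 to day 5 had opposite signs without and with vitamin C. Mean methylation differed by 2.19 points in untreated cells and 2.71 with L-proline, and by -0.708 with vitamin C and -0.432 with both, a gap of 3.02 points. It was 1.53 at 30 reads and 7.12 over all CpGs listed for each library. The gap drew attention because all libraries without vitamin C moved one way and all with it the other. An exact two-sided permutation test of the 4 differences gave p = 0.333, the smallest that 6 groupings allow, so chance cannot be told apart from an effect with so few values. The limma test of a vitamin C by day term called 0 tiles, with 6193 of 50167 at an unadjusted p under 0.05. Incomplete bisulfite conversion would need lambda to show a similar gap, and the gap there was 0.112 points. An effect of vitamin C that grows with time stays open as a hypothesis. With 1 library per treatment and day it cannot be told from differences between cultures.

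The loss of methylation with vitamin C was weighed against chance and conversion. In a limma fit on the split alone, the vitamin C split called 8051 tiles, and 1 of the 35 splits of the 8 libraries into 4 and 4 reached this count, the real one, while the highest of the others was 0. In the other splits the vitamin C difference enters the residual, which pushes their counts towards 0. The real split also parts the 4 libraries of lowest mean methylation from the rest. The comparison therefore shows only that the real split ranks highest, and the size of the contrast carries no further weight. Unconverted lambda cytosines differed by -0.0959 ± 0.143 points (SD, n = 4 pairs) with vitamin C, with an upper 95% bound of at most 1.22% in any library. That is far from the difference of -4.14 points in mean methylation. An effect of vitamin C, the factor named by the design, stays open as a hypothesis, since the pattern was found and tested on the same data. With 1 library per treatment and day, and no culture or batch in the labels, such an effect cannot be told from differences between cultures.

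For L-proline and for day, the real split called 0 tiles in the same fit. With a count of 0, all 35 splits reach it by construction, the highest of the others being 8051 for the vitamin C split, so this comparison says nothing about chance.

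CpGs on unplaced contigs, outside the main comparisons, gave a signal of their own. Over 664 such CpGs covered in all libraries, the matched difference for L-proline was 2.05 ± 0.679 points (SD, n = 4 pairs), higher in 4 of 4. For vitamin C it was -5.004 ± 2.22 points, lower in 4 of 4.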

How the results depend on the processing

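Thinning to 20 reads, library quality weights, classes by untreated cells of the other day, the gap of X to autosomes at 20 reads and interactions with day were added after the data had been seen. The signs of the mean matched differences held in all alternatives run. For vitamin C the value was -1.97 points at 30 reads and stayed within 1 SD otherwise, though over all listed CpGs (-5.41 ± 4.34, n = 4 pairs) the day 2 pair with L-proline fell from -3.02 to -0.187. For L-proline it was 1.34 at 20 reads, 0.923 at 30 reads, 5.23 over all listed CpGs and 3.19 over pooled reads, and within 1 SD otherwise; the day difference stayed within 1 SD throughout. Both supplements against untreated on day 2 turned from -0.780 to 0.716 over pooled reads and to 4.21 over all listed CpGs, where the difference from the sum of the single ones turned from -0.766 to 3.33. The gap in day differences without and with vitamin C ran from 1.53 at 30 reads to 7.12 over all listed CpGs. The means of single libraries moved by more than the margin of the Wilson interval of their pooled reads in 40 values, and by less in 8. That interval is not one of the mean of CpG percentages. It is also narrow (14.05 to 14.08% in untreated cells on day 2), so these counts say little about robustness. Levels moved as well, and the mean without vitamin C was 21.4% in the main set, 12.9% at 20 reads and 8.38% at 30 reads. Classes of like methylation stayed within 1 SD at 20 reads, as given below. The smaller differences at 20 reads therefore went with the CpGs kept. The cause of the other moves was not tested.

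Counts of called CpGs are listed in a fixed order: L-proline, vitamin C and both against untreated, both against L-proline, both against vitamin C, each on day 2 then day 5, and day 5 against day 2 in untreated, L-proline, vitamin C and both. The counts were 601, 4501, 3198, 18416, 365, 3758, 3800, 35368, 2209, 567, 765, 5560, 654 and 138. At an adjusted p under 0.01 they were 125, 1686, 1281, 8622, 85, 1251, 1190, 19749, 894, 102, 165, 2320, 170 and 35. At 20 reads, where fewer CpGs were tested, they were 407, 2817, 1641, 9382, 286, 2213, 2374, 17720, 855, 339, 530, 3713, 358 and 77. At 30 reads they were 179, 1397, 678, 3947, 189, 1150, 1227, 7331, 299, 181, 287, 1793, 153 and 43. Thinned to 20 reads, on the CpGs of the 20 read minimum, they were 0, 31, 6, 700, 1, 40, 1, 1997, 0, 2, 0, 1, 0 and 0, and the lone call for both against untreated on day 2 was higher, against a majority lower in the main count. Thinned to 10 reads all were 0, which is void because so few reads rarely reach the adjusted threshold. With CpGs covered in the 2 libraries alone, both against vitamin C on day 2 gave 3357 calls. The remaining alternatives, differences of 10 and 30 points among them, stayed within 1.5 times.

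For vitamin C tiles, against 11645, the counts were 534 with the quasi-binomial model, 4889 at 20 points, 6605 on the fraction scale, 4285 with 5 or more CpGs, 17633 with 1 or more (4 higher) and 3115 at 20 reads. Centring the libraries gave 1067, of which 932 were higher and 135 lower. It subtracts the same shift from every tile, also from the 20177 tiles under 5% methylation, where the main fit called 0. A gain after centring is therefore relative to that shift and cannot be told from over-correction. With no minimum difference 86 of 17283 were higher, and 1 was higher with 500 bp tiles and 1 without the vitamin C library of day 5. Leaving out each library gave 2742 to 13981, all other alternatives stayed within 1.5 times, and the cause was not tested beyond the fewer libraries or tiles. The quasi-binomial model called 2 tiles for L-proline and 1 for day. Limma called 0 for L-proline, day and each interaction in all alternatives run. The 5 named losses with vitamin C passed on the fraction scale, with other pseudocounts, centring, quality weights, the interaction term and each library left out, and not with the quasi-binomial model. The 5 named gains, which did not pass, passed with centring alone. Tile sizes and coverage were not tried for named tiles.

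In tiles higher with L-proline on day 2, the difference on day 5 between both and L-proline was -24.3 points for a gain of 10, -32.7 for a gain of 30 and -31.2 with 5 or more CpGs. All tiles of the same methylation averaged -21.8, -26.9 and -27.5. Selected on day 5 and measured on day 2 it was -11.5, -12.5 and -12.3, against -10.4, -12.3 and -12.2 for all tiles of the same methylation. The direction held, in the selected tiles and in all tiles of the same methylation alike, and the cause of the moves was not tested. At 20 reads, the 7 methylation classes stayed within 1 SD for both supplements, and of the 5 density classes 2 moved further for each. Classed by untreated cells of the other day, 1 of the 7 classes moved by more than 1 SD for vitamin C, that of 95% or above from -1.46 to -7.17 points, and 3 for L-proline, all in the same direction. Across chromosomes at 20 reads, 18 values moved by more than 1 SD for L-proline and 1 for vitamin C, all in the same direction. The gap of X to autosomes over all CpGs turned at 20 reads, from 1.28 to -0.581 points for vitamin C and from -0.660 to 0.210 for L-proline, and for CpGs of mean methylation 20 to 80% it kept its sign at 1.86 and -1.08 points.

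Summing of strands was not applicable, and promoters and gene lists were not run. The labels give no replicate numbers, so no fit with a replicate block was made beyond the pairs matched on day and supplement.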

Other observations

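The test of CpG density below was set out before its result was seen, and the test within bins and the correlation afterwards.

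Highly methylated tiles differed in their measured loss, and how much of this spread is read noise was not tested. Of the 11426 tiles at 80% or more in untreated cells on day 2, 1863 (16.3%) were lower by at least 20 points with vitamin C than untreated on day 5, and 2964 (25.9%) lay within 5 points. With both supplements 987 (8.64%) were lower by at least 20 points, and with L-proline 1. The mean differences were -10.9 points with vitamin C, -8.09 with both and 3.18 with L-proline. Tiles at 80% or more in all 8 libraries numbered 4171.

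The 164 CpGs called higher with vitamin C on day 2 averaged 68.1% in that library and 25.7% in untreated cells of day 2. In the remaining libraries they averaged 34.0% to 55.0%, and on day 5 the vitamin C library was lower than untreated by a mean difference of -12.9 points. They were chosen for their gap between these day 2 libraries, so levels in between elsewhere follow in part from the choice. Between the same day 5 libraries, all CpGs at 20 to 40% in untreated cells of day 2 differed by -21.8 points. The 164 CpGs were spread over 160 tiles.

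One hypothesis was that CpG density shapes the loss with vitamin C beyond the methylation level. In tiles of mean methylation 20 to 80%, those with 11 or more covered CpGs differed by -17.1 points and those with 3 to 5 by -16.5, a gap of -0.635 ± 1.17 points (SD, n = 4 pairs) with 2 pairs of each sign. The mean levels of these tiles were unequal, at 42.6% and 57.8%. Averaged over 6 bins of 10 points, the gap was 0.320 ± 0.268 points with 3 of 4 pairs positive. Neither version met the condition of one sign in all 4 pairs. For L-proline the gap was -0.310 ± 1.34 points, negative in 3 of 4 pairs, and over bins -1.08 ± 0.335, negative in 4 of 4.

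A further hypothesis was that the same tiles respond to both supplements in opposite directions. Effects of vitamin C and of L-proline taken from different libraries were correlated across tiles within bins of methylation in a library used for neither. Pearson's r ranged from -0.157 to -0.0300 over 4 combinations of libraries, and Spearman's rho from -0.186 to -0.0445, across 17176 to 23228 tiles, which are not independent replicates. Pooled over bins the correlations were negative in all 4 combinations but weak. Within single bins Pearson's r was negative in 5, 4, 6 and 8 of 8, with highest bins of 0.0578, 0.0281, 0.0600 and -0.0378. Read noise lowers them by an unknown amount, so these values do not decide the question.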
